A study of Mus musculus with 11 samples.

How the data were processed

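RNA was sequenced from mouse microglia, the macrophages of the brain parenchyma, in 11 libraries. The labels give every library the Cx3cr1-GFP genotype, in which microglia carry a green fluorescent reporter. The groups were 3 libraries of cultured primary microglia, 4 of resident microglia and 4 of transplanted microglia, the last 2 groups isolated by fluorescence-activated cell sorting. Transplanted cells were collected 3 months after transplantation. Per the labels' protocols, mice ate chow with 600 mg/kg PLX3397, an inhibitor of the receptor Csf1r on which microglia depend, in 3 depletion cycles before cells were transplanted. The labels attach this protocol to every library, so they do not say whether the mice that gave resident cells were treated. They also do not say whether the transplanted cells came from the cultured cells or from another source. Per the labels' protocols, RNA was extracted with TRIzol and 1 ng was made into cDNA libraries with a Smart-Seq protocol, which primes on poly(A) tails and is commonly unstranded; the labels do not give strand. Libraries were grouped by their titles. The labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

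The deposited table holds 16894 genes by Entrez identifier, with an expected read count, a TPM and an FPKM for each library, per the file headers. The expected counts were estimated by the authors and are not scaled to library size, and 81.5% to 84.9% of the values in a library are whole. The TPM values were scaled by the authors for gene length and library, and each column has the same sum. Per the submitters' processing notes, HISAT, Bowtie2 and the genome build GRCm38.p6 were used. Their versions, the read counter, the gene annotation and any filter are not given in the sources used here. The 11 FPKM columns were not used. Gene symbols and coordinates came from a RefSeq gene table of the same build, GRCm38.p6, which matched 16845 of the 16894 identifiers (99.7%); the other 49 stayed in the tests without a symbol. Reads of genes with near-identical copies, such as ribosomal protein genes with their pseudogenes, H2 genes of MHC class I, Ifi204, Klra2 and Ear2, may have been split or shared by the authors' counting, and their values are uncertain to that extent.

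Total expected counts were 26705034 to 28219696 per cultured library, 19055655 to 19965631 per resident library and 18692721 to 19761208 per transplanted library. At these depths 3 counts, the upper limit that a count of 0 allows, correspond to 0.136 to 0.146 in a library, in counts scaled to a common library total (CPM). Where every library of a group was at 0, the fold is given as a lower bound against 3 counts over the group. Where a group had 1 to 3 counts, the ratio of levels is given with an exact Poisson interval at 95%. The libraries carry no molecular identifiers, so intervals and floors cover counting error only.

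Expected counts were rounded to whole numbers. Each pair of groups was fitted alone with edgeR 4.0.16 in R 4.3.3, with TMM scaling, edgeR's filter on expression and the quasi-likelihood test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested; every adjusted p of a single gene below comes from this test. Levels are CPM with TMM scaling over all 11 libraries, as mean ± SD, and the error of a log2 fold change is its standard error. Lists of genes (33 in all: microglial states, pathways, organelles and markers of other cell types) were tested with camera in limma 3.58.1 at its preset inter-gene correlation of 0.01, for lists with at least 5 members tested. Its p-values were adjusted over the 78 list tests of the 3 comparisons together. Every call of a list is set beside the adjusted p with the correlation estimated from the data, and counts of called members are given over all genes and adjusted over the list alone. The lists were drawn up from general knowledge of these cells; none was chosen by the study on these samples.

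The position of transplanted cells between the other groups was computed per gene as the transplanted minus the cultured mean, divided by the resident minus the cultured mean, on log2 CPM with a prior count of 1, so that 0 is the cultured and 1 the resident level. It was summarised over genes called between cultured and resident cells with at least a 2-fold difference, and again with the resident libraries split, so that the resident libraries that chose the genes did not set the resident level (6 splits). The cultured libraries were not split. Transplanted and cultured cells were both compared with the same resident libraries. The correlation and covariance of those comparisons were therefore set beside 100 simulations of fold changes with unchanged groups.

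The lists, groups, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 6 highest and 6 lowest log2 fold changes among called genes whose groups did not overlap and whose level was above the median of the genes tested, without predicted genes, clones or pseudogenes. It also took, per list described, up to 4 called members with the largest change, or the 2 members with the highest level where none was called. It finally took Tmem119, P2ry12, Sall1, Cx3cr1, Csf1r, Apoe, Ms4a7, Clec12a and Mki67 in every comparison. Some genes that the rule took are not reported here. Genes named as the most abundant of a library were taken by that rank. Any other gene named below was chosen after its values were seen, and the text says so.

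The tests were checked on simulated counts drawn from these libraries' means and sizes with 200 genes changed. For transplanted against resident cells, edgeR recovered 58.2% of 67 genes changed 1.5-fold, 88.1% of 67 changed 2-fold and 100% of 66 changed 4-fold among 11843 genes, with 9 unchanged genes called. For cultured against resident cells the shares were 15.2%, 60.0% and 92.4% among 12268 genes, and for transplanted against cultured cells 9.0%, 54.5% and 87.9% among 12141 genes. Camera called a simulated list changed 1.5-fold in each comparison, and for transplanted against resident cells also 1 unchanged list (4.76%). Calls in correlated lists, or with most genes changed, were not checked. A simulated position of 0.8 was recovered as 0.8 over 6311 genes. Over 12386 genes, the check against random lists of equal transcript length left an excess of 0.17 log2 units with a length trend alone. It left 1.17 with a shift of 1 added.

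No library was a duplicate of another. The chi-square of counts per degree of freedom was 8.16 or more in each pair of libraries of 1 group. The alternatives tried were DESeq2 size factors, no filter and a stricter filter of 10 counts, the Wald test of DESeq2 1.42.0, limma-voom with sample weights, 1 fit of all 3 groups, the replicate number as a block, a 2-fold minimum, an estimated correlation for lists, and each library left out in turn. Added after seeing the data were limma with an intensity trend on log2 of the deposited TPM plus 1, a fit with each library's trend on transcript length removed, and fits without transplanted replicates 1 and 2. Relative transcript length was read from the ratio of a gene's expected count to its TPM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.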

Results

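RNA of mouse brain microglia was measured in expected read counts over 16894 genes. The 11 libraries were 3 of cultured, 4 of sorted resident and 4 of sorted transplanted cells. The series asks how far transplanted cells take up the expression programme of naive microglia, with cultured and resident cells as the reference groups. Between 13361 and 13860 genes were detected per cultured library, the deepest, 14279 to 14595 per resident and 14197 to 14476 per transplanted library. The 10 most abundant genes held 25.1% to 26.5% of counts in cultured libraries, against 12% to 13.2% in resident and 11.9% to 13.2% in transplanted libraries. Apoe, which encodes a lipid-carrying apolipoprotein, was the most abundant gene in each cultured library at 6.23% to 6.67% of counts. The protease inhibitor gene Cst3 led each resident library at 2.27% to 2.71%, and Ctsd, which encodes the lysosomal protease cathepsin D, led each transplanted library at 2.41% to 2.81%.

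Transplanted microglia lay close to resident microglia and far from cultured microglia. Over 12646 genes, group means on the log2 CPM scale differed by a root mean square of 0.63 between transplanted and resident cells, 2.37 between cultured and resident cells and 2.22 between transplanted and cultured cells. Across genes, which are not independent replicates, the means of transplanted and resident cells had a Pearson correlation of 0.975, against 0.679 for cultured and resident cells. Libraries of 1 group correlated at 0.959 to 0.977 (cultured), 0.977 to 0.988 (resident) and 0.979 to 0.985 (transplanted). The first principal component, with 83.4% of the variance, separated cultured from sorted cells, and the second, with 5.6%, separated resident from transplanted cells.

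**Figure D1:**
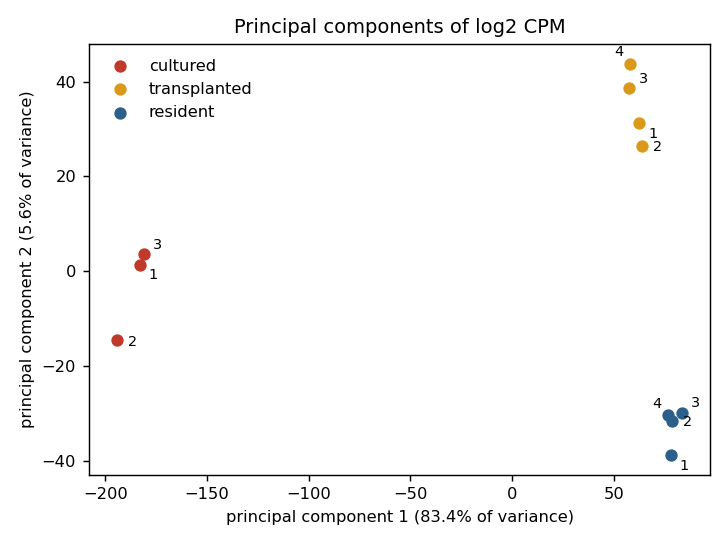
Principal components 1 (83.4% of variance) and 2 (5.6%) of log2 CPM over 12646 genes; each point is a library, coloured by group. The 3 cultured libraries stand apart along component 1, and the 4 resident and 4 transplanted libraries separate along component 2.

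Cultured and resident microglia are the reference states of the design. Cultured cells had low expression of genes that mark microglia in the brain and carried high levels of macrophage, lipid, matrix and proliferation genes. Tmem119, a surface marker of brain microglia (Entrez 231633, chromosome 5: 113793729 to 113800396, GRCm38.p6), stood at 11.8 ± 2.6 CPM in cultured cells (SD, n = 3) against 6100 ± 345 in resident cells (SD, n = 4), which is 503-fold lower (log2 fold change -8.98 ± 0.22, adjusted p = 6.03e-09). Apoe (Entrez 11816, chromosome 7: 19696244 to 19701310) was 162-fold higher, at 85100 ± 2900 against 539 ± 165 CPM (7.34 ± 0.25, adjusted p = 2.28e-08). Of 12406 genes tested, 4704 were higher and 4612 lower in cultured cells. Of these, 3113 higher and 3110 lower genes differed at least 2-fold. The groups did not overlap at 75.7% of the genes tested, against 5.71% by chance.

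All 25 homeostatic microglia genes, which mark cells in the undisturbed brain, were lower in cultured cells, with a median log2 fold change of -5.44. The list test gave an adjusted p of 2.67e-32, and adjusted p = 0.023 with an estimated correlation. The sialic acid-binding receptor Siglech had a log2 fold change of -11.80 ± 0.27 (0.74 ± 0.264 against 2730 ± 139 CPM), and the adhesion receptor Adgrg1 one of -10.07 ± 0.22. P2ry12, the receptor with which microglia sense nucleotides (Entrez 70839, chromosome 3: 59216271 to 59262985), stood at -7.06 ± 0.28 and the fractalkine receptor Cx3cr1 at -4.58 ± 0.13. Csf1r, the receptor on which microglial survival depends, stood at -2.23 ± 0.23 (adjusted p = 1.83e-05). The uroplakin gene Upk1b had 1 count over the cultured libraries, a ratio of 13400 below the resident level (95% counting interval 2400 to 528000). That count lay in cultured replicate 3, and the other 2 libraries had 0. Of 14 microglial transcription factors, 10 were lower and 2 higher (median -1.10, list adjusted p = 9.55e-05, and adjusted p = 0.171 with an estimated correlation). Sall1, which maintains microglial identity (Entrez 58198, chromosome 8: 89027242 to 89044162), stood at -7.15 ± 0.27, Sall3 at -5.50 ± 0.16 and Ets1 at -4.46 ± 0.11. The number of higher factors was 1 without cultured replicate 2 or resident replicate 2, 3 or 4. Of 15 TGF-beta pathway genes, 9 were lower and 3 higher, and the list was not called (median -0.59, adjusted p = 0.0715, and p = 0.339 with an estimated correlation), although it was without cultured replicate 2 (median -0.80, adjusted p = 0.0342). The receptor Tgfbr1 stood at -4.45 ± 0.17 and Smad3, which carries its signal, at -2.67 ± 0.11. The counts adjusted over the list alone were the same except for TGF-beta genes, with 10 lower and 4 higher.

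Genes of activated and engrafted macrophages were higher in cultured cells. Of 23 disease-associated microglia genes, 19 were higher and 3 lower (median 2.30, list adjusted p = 1.21e-09, and adjusted p = 0.10 with an estimated correlation). Among them were Gpnmb (12.68 ± 0.45), the osteopontin gene Spp1 (11.67 ± 0.71, 22600 ± 249 against 7.15 ± 4.98 CPM) and the galectin gene Lgals3 (9.61 ± 0.26). Of 14 lipid handling genes, 13 were higher and 1 lower (median 4.94, adjusted p = 1.68e-07, and adjusted p = 0.023 with an estimated correlation). They included the fatty acid-binding protein genes Fabp5 (9.67 ± 0.25) and Fabp4, which had no count in resident cells and was at least 136-fold higher. Of 18 adhesion and matrix genes, 15 were higher and 2 lower (median 8.26, adjusted p = 9.47e-15, and adjusted p = 0.0147 with an estimated correlation). Fibronectin, Fn1, stood at 12.70 ± 0.71 and annexin A2, Anxa2, at 10.25 ± 0.23. Of 13 genes of engrafted blood-derived macrophages, 11 were higher and 1 lower (median 5.72, adjusted p = 1.64e-08, and adjusted p = 0.10 with an estimated correlation). The lysozyme gene Lyz2 stood at 7.93 ± 0.20, Clec12a at 6.81 ± 0.22 and Ms4a7 at 4.47 ± 0.27. Of 13 monocyte markers, 12 were higher and 1 lower (median 6.52, adjusted p = 7.97e-11, and adjusted p = 0.0255 with an estimated correlation). Of 13 border-associated macrophage markers, 8 were higher and 3 lower (median 4.36, adjusted p = 0.00188, and adjusted p = 0.314 with an estimated correlation). The platelet factor gene Pf4 stood at 8.03 ± 0.34, and Cd209f had 0 counts in cultured cells and was at least 102-fold lower. With 1 library left out, no monocyte marker was lower without resident replicate 2, 3 or 4, and 2 genes of engrafted macrophages were lower without resident replicate 1 or 2. Each of these counts was the same adjusted over the list alone. Setting genes with a group at 0 to their bound left every list median in the 3 comparisons at the same 2 decimals.

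Of 24 inflammatory cytokine genes, 20 were higher and 1 lower in cultured cells (median 2.70, adjusted p = 1.15e-05, and adjusted p = 0.239 with an estimated correlation). The acute-phase gene Saa3 had 3 counts in resident cells, a ratio of 9080 (3110 to 44000), and the chemokine gene Cxcl2 was higher by 9.18 ± 0.20. Arg1, the arginase of alternatively activated macrophages (Entrez 11846), was higher by 13.22 ± 0.73 (26900 ± 2950 against 2.89 ± 1.94 CPM, adjusted p = 3.55e-07). Of 21 immediate early genes, 7 were higher and 4 lower, and the list was not called (adjusted p = 0.579, and p = 0.949 with an estimated correlation). This depended on resident replicate 1, which stood apart in these genes: without it 17 members were higher, with a median of 4.50 and a list adjusted p of 4.59e-10. The nuclear receptor gene Nr4a1 stood at 6.09 with all libraries and at 7.73 without resident replicate 1. The number of lower members was 2 without any 1 of the cultured libraries. Of 21 complement and phagocytic receptor genes, 13 were higher and 6 lower (median 0.57, adjusted p = 0.0303, and adjusted p = 0.497 with an estimated correlation), with the scavenger receptor Msr1 at 8.11 ± 0.25 and Cd36 at 6.32 ± 0.30. This list was not called without cultured replicate 2 (median 0.62, adjusted p = 0.0653), and its median was -0.55 on the TPM scale. Of 5 neutrophil markers, 3 were higher and 2 lower (median 8.14, adjusted p = 0.0379, and adjusted p = 0.202 with an estimated correlation), and this list too was not called without cultured replicate 2 (median 7.86, adjusted p = 0.154). The collagenase gene Mmp8 had no count in resident cells and was at least 1030-fold higher, while the granulocyte colony-stimulating factor receptor gene Csf3r stood at -3.29 ± 0.34. The counts in these 4 lists were the same adjusted over the list alone.

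Proliferation and metabolic genes were higher in cultured cells. Of 32 cell cycle genes, 31 were higher and none was lower (median 4, adjusted p = 2.07e-13, and adjusted p = 0.078 with an estimated correlation). Mki67, a marker of cycling cells, stood at 4.41 ± 0.20 and cyclin B2, Ccnb2, at 5.53 ± 0.22. Of 15 glycolysis genes, 14 were higher (median 3.64, adjusted p = 3.21e-11, and adjusted p = 0.0634 with an estimated correlation), with Gpi1 at 4.53 ± 0.12 and lactate dehydrogenase, Ldha, at 4.16 ± 0.12. All 27 nuclear-encoded respiratory chain genes (median 2.17, adjusted p = 1.07e-07, and adjusted p = 0.30 with an estimated correlation) and all 25 cytosolic ribosomal protein genes (median 2.88, adjusted p = 3.55e-09, and adjusted p = 0.404 with an estimated correlation) were higher. These transcripts are short, and in this comparison the median log2 fold change was 1.38 over the shortest 10% of genes and -0.47 over the longest 10%. With each library's trend on length removed, the respiratory median was 0.77 and the ribosomal median 1.46. Of 24 lysosome genes, 17 were higher and 1 lower (median 0.89, adjusted p = 0.00702, and adjusted p = 0.467 with an estimated correlation). Of 19 cholesterol synthesis genes, 13 were higher (median 0.83, adjusted p = 0.00672, and adjusted p = 0.456 with an estimated correlation). On the TPM scale both medians were below 0, at -0.27 for lysosome and -0.32 for cholesterol synthesis genes. Without cultured replicate 2 the lysosome list had 20 higher and 2 lower members. Of 13 unfolded protein and amino acid stress genes, 4 were higher, with asparagine synthetase, Asns, at 5.44 ± 0.23, and 8 lower, with Herpud1 at -2.21 ± 0.18. Their median was -0.45 and their mean 0.30, with the test in the lower direction, and the list was not called (adjusted p = 0.964, and p = 0.982 with an estimated correlation). Each of these 7 lists gave the same counts adjusted over the list alone.

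Antigen presentation and interferon genes were mixed between cultured and resident cells. Of 13 MHC class II and costimulation genes, 8 were lower and 1 higher in cultured cells (median -1.12, adjusted p = 0.00702, and adjusted p = 0.314 with an estimated correlation), with H2-Eb1 at -5.43 ± 0.40 and H2-Ob at -4.75 ± 0.15. Of 11 MHC class I genes, 7 were higher and 3 lower (median 0.97), and the list was not called (adjusted p = 0.575, and p = 0.791 with an estimated correlation). Its median was -0.09 on the TPM scale and -0.01 with the length trend removed. H2-D1 was higher by 1.82 ± 0.15 and B2m, the class I light chain, by 1.21 ± 0.12, but B2m stood at -0.09 with the length trend removed and was not called on the TPM scale. Of 21 interferon response genes, 10 were higher and 3 lower (10 and 2 adjusted over the list alone), with Ifitm3 at 6.11 ± 0.38. The median of 0.19 was -0.29 on the TPM scale, and the list was not called (adjusted p = 0.131, and p = 0.738 with an estimated correlation), although it was without resident replicate 4 (median 0.75, adjusted p = 0.00126). The MHC counts were the same adjusted over the list alone.

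Astrocyte, oligodendrocyte, neuron and endothelial markers gave no called list between cultured and resident cells. Of 5 astrocyte markers, 2 were higher and 2 lower (list adjusted p = 0.597, and p = 0.822 with an estimated correlation), with Aldoc at 5.07 ± 0.40. Of 5 oligodendrocyte markers, 1 was higher and 1 lower (adjusted p = 0.725, and p = 0.827 with an estimated correlation). Of 5 neuron markers, 4 were lower and none higher (adjusted p = 0.514, and p = 0.599 with an estimated correlation), and of 6 endothelial markers 3 were higher and 3 lower (adjusted p = 0.997, and p = 0.998 with an estimated correlation). With 1 library left out, 1 astrocyte marker was lower without resident replicate 2, 3 or 4, 1 neuron marker was higher without cultured replicate 1 and 2 oligodendrocyte markers were lower without cultured replicate 3. The oligodendrocyte marker Mbp was higher by 0.97 ± 0.10 but stood at -0.16 on the TPM scale, and Mag stood at -1.85 ± 0.12. The endothelial adhesion gene Pecam1, which macrophages also express, stood at -3.09 ± 0.25, with 5.41 ± 1.91 against 47.3 ± 7.61 CPM. Of lists with under 5 members tested, which had no list test, 3 of 3 oligodendrocyte precursor markers were higher (Cspg4 at 6.30 ± 0.35) and 2 of 2 mural cell and fibroblast markers were higher (Col1a1 at 3.56 ± 0.61). Of 2 lymphocyte markers, 1 was higher (Cd8a at 1.73 ± 0.41) and 1 lower (Cd79b, the B cell receptor chain, at -4.18 ± 0.29). These counts were the same adjusted over the list alone. Erythroid and mitochondrially encoded genes had no member tested in any comparison, and no mitochondrially encoded gene was in the table. Of 4 sex-linked genes, Uty was called lower (-0.86 ± 0.29, adjusted p = 0.0232) but not adjusted over the list alone, nor without cultured replicate 2 (-0.84, adjusted p = 0.0509), cultured replicate 3 (-0.89, 0.0508) or resident replicate 2 (-0.73, 0.0559). Resident replicate 4 had almost no counts of the Y-linked genes Ddx3y (0.137 CPM), Kdm5d and Eif2s3y, while Uty was at 21.2 CPM, and without this library 1 sex-linked gene was called higher and 1 lower.

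Cultured libraries were dominated by fewer genes, and some differences from them changed direction in the fit of TPM values. On the deposited TPM scale, tested with limma as an alternative added after the data were seen, the median log2 fold change was shifted by -1.05, and 1993 genes were higher and 7830 lower. Of calls, 20.3% were higher, against 50.5% with TMM-scaled counts, and 1005 genes were called in opposite directions, while 0 were with DESeq2 size factors. The TPM fit also changed the test, the filter and the length scaling.

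**Figure D2:**
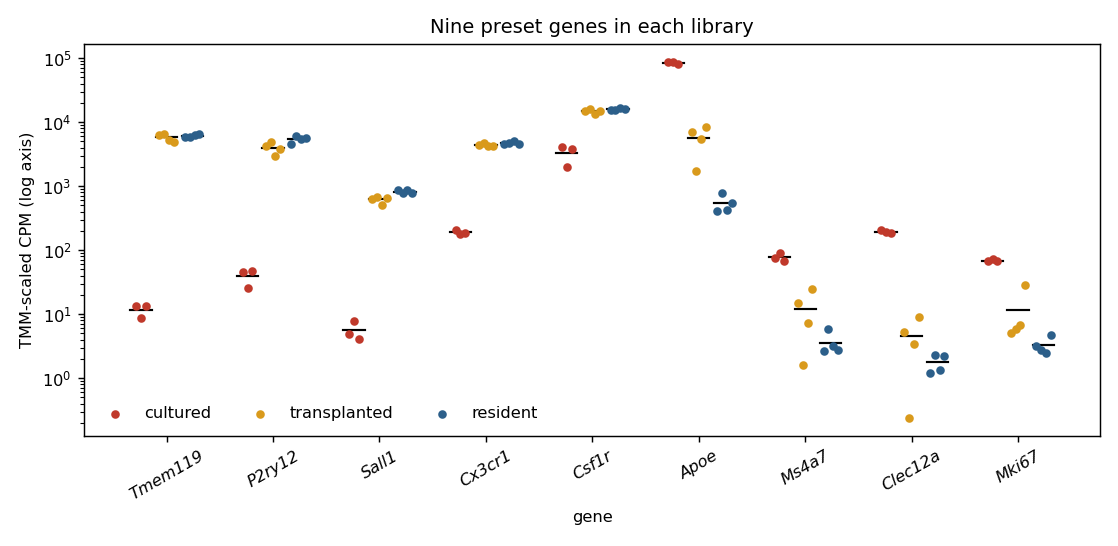
TMM-scaled CPM (log axis) of 9 genes fixed beforehand, in each of the 11 libraries; points are libraries and black lines are group means. Tmem119 lies between 11.8 CPM (mean of 3 cultured libraries) and 6100 CPM (mean of 4 resident libraries), with transplanted cells at a mean of 5760.

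Transplanted cells were next compared with cultured cells. Transplanted microglia expressed microglial marker genes far above the cultured level and had low levels of many genes abundant in culture, such as Arg1. Tmem119 stood at 5760 ± 846 CPM in transplanted cells (SD, n = 4), 483-fold above cultured cells (n = 3; 8.92 ± 0.26, adjusted p = 5.59e-09), and Sall1 at 619 ± 78.1, 109-fold above (6.77 ± 0.28, adjusted p = 3.45e-08). Arg1 stood at 4.02 ± 2.59 CPM, at a log2 fold change of -12.72 ± 0.50 (adjusted p = 2.9e-08). Of 12284 genes tested, 4530 were higher and 4361 lower in transplanted cells, with 3115 and 3021 differing at least 2-fold. The groups did not overlap at 73.3% of genes, against 5.71% by chance.

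All 25 homeostatic microglia genes were higher in transplanted than in cultured cells (median 4.94, adjusted p = 3.38e-38, and adjusted p = 0.0434 with an estimated correlation). Siglech stood at 11.42 ± 0.28, P2ry12 at 6.63 ± 0.31, Cx3cr1 at 4.52 ± 0.14 and Csf1r at 2.14 ± 0.24. Of 14 microglial transcription factors, 10 were higher and 2 lower (median 1.17, adjusted p = 4.94e-05, and adjusted p = 0.0634 with an estimated correlation), with Sall3 at 5.65 ± 0.16 and Ets1 at 3.89 ± 0.13. Of 15 TGF-beta pathway genes, 9 were higher and 3 lower (9 and 4 adjusted over the list alone), with Tgfbr1 at 4.36 ± 0.20. That list had a median of 0.65 (adjusted p = 0.0438, and adjusted p = 0.239 with an estimated correlation) and was not called without cultured replicate 1 (median 0.51, adjusted p = 0.0706). Of 13 MHC class II and costimulation genes, 8 were higher, with H2-Ob at 4.38 ± 0.20, and 2 lower, with H2-Ab1 at -2.19 ± 0.25 (median 1.08). These were not called as a list (adjusted p = 0.0698, and p = 0.497 with an estimated correlation), but were without transplanted replicate 3 (median 1.18, adjusted p = 0.0329). Apart from TGF-beta genes, the counts adjusted over the list alone were the same.

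Of 23 disease-associated microglia genes, 17 were lower and 2 higher in transplanted than in cultured cells (median -2.03, adjusted p = 2.36e-10, and adjusted p = 0.0719 with an estimated correlation), with Gpnmb at -10.85 ± 0.36, Spp1 at -10.39 ± 0.28 and Apoe at -3.94 ± 0.43. Inflammatory cytokine genes were lower in 19 of 24 and higher in 1 (median -2.69, adjusted p = 7.65e-14, and adjusted p = 0.0147 with an estimated correlation), with the chemokine Ccl7 at -10.04 ± 0.21. Immediate early genes were lower in 17 of 21 and higher in 4 (median -3.94, adjusted p = 1.21e-09, and adjusted p = 0.0634 with an estimated correlation), with Egr2 at -8.16 ± 0.19. Adhesion and matrix genes were lower in 15 of 18 and higher in 2 (median -7.66, adjusted p = 8.33e-16, and adjusted p = 0.0147 with an estimated correlation), with Fn1 at -10.86 ± 0.33. Lipid handling genes were lower in 12 of 14 and higher in 1 (13 and 1 adjusted over the list alone, median -4.63, adjusted p = 3.21e-07, and adjusted p = 0.023 with an estimated correlation), with Fabp5 at -7.99 ± 0.24. Genes of engrafted blood-derived macrophages were lower in 10 of 13 and higher in 2 (median -3.94, adjusted p = 4.03e-05, and adjusted p = 0.184 with an estimated correlation), with Lyz2 at -6.86 ± 0.20. Border-associated macrophage markers were lower in 9 of 10 (median -5.41, adjusted p = 6.42e-08, and adjusted p = 0.023 with an estimated correlation), with Pf4 at -9.92 ± 0.37. Monocyte markers were lower in 11 of 12 and higher in 1 (median -5.64, adjusted p = 2.58e-12, and adjusted p = 0.0147 with an estimated correlation). Neutrophil markers were lower in 3 of 5 and higher in 2 (median -7.58, adjusted p = 0.0296, and adjusted p = 0.189 with an estimated correlation), with Csf3r at 3.73 ± 0.34. The neutrophil list was not called without cultured replicate 2 (median -7.32, adjusted p = 0.0864), and 1 of its markers was higher without any 1 of the other libraries. Without cultured replicate 2, 2 inflammatory cytokine genes were higher. The counts were the same adjusted over the list alone apart from lipid handling genes.

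Of 32 cell cycle genes, 30 were lower in transplanted than in cultured cells (median -2.47, adjusted p = 0.000136, and adjusted p = 0.456 with an estimated correlation). The tubulin-binding gene Stmn1 stood at -3.40 ± 0.31 and Mki67 at -2.60 ± 0.54, or -3.55 without transplanted replicate 4. Glycolysis genes were lower in 14 of 15 and higher in 1 (median -3.79, adjusted p = 3.38e-17, and adjusted p = 0.0318 with an estimated correlation), with Pgk1 at -4.65 ± 0.15. All 27 respiratory chain genes (median -2.40, adjusted p = 1.1e-10, and adjusted p = 0.202 with an estimated correlation) and all 25 ribosomal protein genes (median -3.02, adjusted p = 4.54e-13, and adjusted p = 0.314 with an estimated correlation) were lower. With the length trend removed these medians were -0.83 and -1.57. Lysosome genes were lower in 16 of 24 and higher in 2 (median -0.68, adjusted p = 0.00633, and adjusted p = 0.456 with an estimated correlation), with the proton pump subunit Atp6v0d2 at 0 counts in transplanted cells and at least 6020-fold lower. Cholesterol synthesis genes were lower in 13 of 19 (median -0.83, adjusted p = 0.0149, and adjusted p = 0.456 with an estimated correlation). On the TPM scale these last medians were 0.37 and 0.36. Adjusted over the list alone the counts were the same, and without cultured replicate 3 no glycolysis gene and 1 cholesterol synthesis gene was higher. Complement and phagocytic receptor genes were lower in 11 of 21 and higher in 6, with a median of -0.56, or 0.56 on the TPM scale (adjusted p = 0.131, and p = 0.51 with an estimated correlation). MHC class I genes were lower in 4 of 11 and higher in 5, with a median of 0.55 and the test in the lower direction (adjusted p = 0.997, and p = 0.998 with an estimated correlation). Interferon response genes were lower in 7 of 21 and higher in 7, with Usp18 at 2.48 ± 0.29 and Ifitm3 at -5.29 ± 0.29. Their median was 0.01, or -0.02 with DESeq2 size factors, and their mean -0.37, with the test in the lower direction (adjusted p = 0.688, and p = 0.949 with an estimated correlation). Without transplanted replicate 3 the interferon genes higher numbered 4. Unfolded protein and amino acid stress genes were lower in 4 of 13 and higher in 8, with a median of 0.78, a mean of -0.03 and the test in the higher direction (adjusted p = 0.401, and p = 0.519 with an estimated correlation). None of these 4 lists was called, and their counts were the same adjusted over the list alone. H2-D1 stood at -1.06 ± 0.15 and B2m at -0.98 ± 0.13, but at 0.04 and 0.14 on the TPM scale, and B2m at 0.41 with the length trend removed.

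Astrocyte, neuron and endothelial markers gave no called list between transplanted and cultured cells. Of 5 astrocyte markers, 2 were higher and 2 lower (adjusted p = 0.968, and p = 0.989 with an estimated correlation), and of 6 neuron markers 2 were higher (adjusted p = 0.594, and p = 0.668 with an estimated correlation). Of 6 endothelial markers, 3 were higher and 3 lower, with the median at -0.09 and the test in the higher direction (adjusted p = 0.945, and p = 0.949 with an estimated correlation). The neuron markers called were Gad1 and Snap25 (3.12 and 2.88), which among cultured libraries had counts in replicate 3 alone, at 0.731 and 0.682 CPM. Without that library the fitted values were 8.52 and 8.18, against 0 counts in the other cultured libraries, so that these sizes are no measured fold. Snap25 was not called without cultured replicate 1 (2.30, adjusted p = 0.0547) or transplanted replicate 2 (2.63, 0.0525), while 4 neuron markers were higher without transplanted replicate 3 and 1 was lower without cultured replicate 1. Of markers too few for a list test, 1 of 4 oligodendrocyte markers was higher (Mag at 1.97 ± 0.14) and 1 lower (Mbp at -0.81 ± 0.11, or 0.27 on the TPM scale). Of these, 2 were lower without cultured replicate 2 and 2 higher without cultured replicate 3. The 3 oligodendrocyte precursor markers and 2 mural cell and fibroblast markers tested were lower (Olig1 at -3.25 ± 0.47, Col1a1 at -3.03 ± 0.41). Both lymphocyte markers tested were lower (Cd79b at -1.76 ± 0.46), and 1 was without cultured replicate 1 or 2 or transplanted replicate 2, 3 or 4. Of 4 sex-linked genes, Uty was higher (1.01 ± 0.24) and Eif2s3y lower (-1.53 ± 0.42). Cd79b was not called with the replicate number as a block, on the TPM scale or with the length trend removed, Uty not with the length trend removed, and Eif2s3y not in 1 fit of all 3 groups or on the TPM scale. The counts were the same adjusted over the list alone. On the TPM scale the median log2 fold change was shifted by 1.04, and 7755 genes were higher and 1843 lower. Of calls, 80.8% were higher, against 51% with TMM-scaled counts, and 730 genes were called in opposite directions.

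The comparison of transplanted with resident cells asks what set cells apart 3 months after transplantation. Tmem119, Cx3cr1 and Csf1r stood near the resident level in transplanted cells, while Apoe, Axl, Ccr1 and Cd44 were higher and H2-Aa, Cd163 and Upk1b were lower. Tmem119 was at 5760 ± 846 CPM in transplanted and 6100 ± 345 in resident cells (SD, n = 4 each), a log2 fold change of -0.08 ± 0.10 (adjusted p = 0.663). Ccr1, a receptor for inflammatory chemokines (Entrez 12768, chromosome 9: 123962126 to 123968692), showed the largest rise among the named genes, 42.7-fold from 5.42 ± 1.09 to 231 ± 92.5 CPM (5.42 ± 0.36, adjusted p = 1.17e-05). Apoe was 10.4-fold higher, at 5600 ± 2800 against 539 ± 165 CPM (3.38 ± 0.42, adjusted p = 0.000536).

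Of 11929 genes tested, 855 were higher and 699 lower in transplanted than in resident cells, together 13%, with 288 and 303 differing at least 2-fold. The groups did not overlap at 19.7% of genes, against 2.86% by chance. The median size of the called changes was 0.72 on the log2 scale, against 1.44 between cultured and resident cells. With 1 library left out the count of higher genes ranged from 511 to 875. It was 519 without resident replicate 2 and 511 without resident replicate 3. That of lower genes ranged from 509 to 878. In transplanted replicates 1 and 2 the Y-linked gene Ddx3y stood at 45.1 and 31.4 CPM, against 118 and 116 in replicates 3 and 4. Without replicates 1 and 2, an alternative chosen after the data were seen, 1374 genes were higher and 1222 lower.

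Besides Ccr1 and Apoe, the highest rises that the rule took among genes above the median level were those of Hcar2, a receptor for hydroxybutyrate and niacin (3.84 ± 0.37, adjusted p = 0.000109), and of Axl, a receptor tyrosine kinase that binds apoptotic cells (Entrez 26362, chromosome 7: 25756500 to 25788924, 3.67 ± 0.30, adjusted p = 3.67e-05). They were followed by the myosin gene Myo5a (2.80 ± 0.23, adjusted p = 3.67e-05) and Cybb, a subunit of the phagocyte oxidase (2.76 ± 0.41, adjusted p = 0.0016). The lowest values that it took among those genes were those of Pde2a, a cyclic nucleotide phosphodiesterase (Entrez 207728, chromosome 7: 101421691 to 101512829, -3.61 ± 0.27, adjusted p = 2.24e-05), and Upk1b (Entrez 22268, chromosome 16: 38773182 to 38800203, -3.20 ± 0.30, 23.3 ± 10.7 against 215 ± 18.2 CPM, adjusted p = 9.5e-05). Next came the receptor phosphatase Ptprm (-3.04 ± 0.18, adjusted p = 6.9e-06), the calcium sensor Ncs1 (-2.43 ± 0.16, adjusted p = 8.69e-06), the collagen receptor Mrc2 (-2.42 ± 0.34, adjusted p = 0.00115) and Csmd3 (-2.35 ± 0.25, adjusted p = 0.000196). Each was called the same way with any 1 library left out.

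Of 25 homeostatic microglia genes, 5 were lower, 1 was higher and 19 were not called (11 lower and 1 higher adjusted over the list alone). Slc2a5, a fructose transporter, fell by 0.82 ± 0.12 (790 ± 123 against 1400 ± 142 CPM, adjusted p = 0.0014), the crystallin gene Crybb1 by 0.87 ± 0.14 and Upk1b as above, while Olfml3 rose by 0.40 ± 0.09 (adjusted p = 0.011). The list median was -0.18 and the list was called lower (adjusted p = 9.76e-05, and adjusted p = 0.404 with an estimated correlation). P2ry12 stood at -0.45 ± 0.14 (adjusted p = 0.0598) and was called without resident replicate 1 (-0.54, adjusted p = 0.0475) or transplanted replicate 2 (-0.58, adjusted p = 0.0168). Cx3cr1 at -0.08 ± 0.07 and Csf1r at -0.11 ± 0.07 were not called (adjusted p = 0.468 and 0.299). The lower members numbered 8 without resident replicate 1, 12 without transplanted replicate 2 and 12 without transplanted replicates 1 and 2. Of 14 microglial transcription factors, 2 were lower (3 adjusted over the list alone) and the list was not called (median -0.01, adjusted p = 0.226, and p = 0.55 with an estimated correlation). Ets1 fell by 0.59 ± 0.06 (adjusted p = 0.000152) and Sall1 by 0.40 ± 0.10 (619 ± 78.1 against 820 ± 58.1 CPM, adjusted p = 0.0271), but Sall1 missed the threshold without resident replicate 1 (-0.38, adjusted p = 0.0527), resident replicate 3 (-0.40, 0.065) or transplanted replicate 1 (-0.41, 0.0504), leaving 1 lower factor. Of 15 TGF-beta pathway genes, only Tgfbi was called (0.88 ± 0.11, adjusted p = 0.000655), also adjusted over the list alone, and the list was not (median 0.04, adjusted p = 0.645, and p = 0.709 with an estimated correlation).

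Of 23 disease-associated microglia genes, 9 rose, 1 fell and 13 were not called (12 and 1 adjusted over the list alone). The list was called (median 0.29, adjusted p = 9.31e-05, and adjusted p = 0.339 with an estimated correlation). Axl stood at 219 ± 74.6 against 17.3 ± 6.15 CPM and Clec7a, a receptor for fungal glucans, at 50.7 ± 17.8 against 11.8 ± 2.28 (2.11 ± 0.23, adjusted p = 0.000229). Of 11 lipid handling genes, 4 rose (also adjusted over the list alone), with Fabp5 at 1.67 ± 0.27 and Soat1, which esterifies cholesterol, at 0.49 ± 0.06 beside Apoe (median 0.32, adjusted p = 0.0219, and adjusted p = 0.142 with an estimated correlation). Of 13 genes of engrafted blood-derived macrophages, 7 rose and 2 fell (9 and 2 adjusted over the list alone). The list was called (median 1.13, adjusted p = 5.98e-05, and adjusted p = 0.222 with an estimated correlation). The risen members included Apoe and Axl, and among the fallen was Ccr2, the receptor that recruits monocytes (-2.23 ± 0.25, 1.53 ± 0.474 against 7.19 ± 1.67 CPM, adjusted p = 0.000301). Ms4a7 stood at 12 ± 9.82 against 3.57 ± 1.49 CPM (1.76 ± 0.62, adjusted p = 0.0954) and Clec12a at 1.36 ± 0.68 (adjusted p = 0.23), and both were called without transplanted replicate 2 (2.11, adjusted p = 0.00815, and 1.74, adjusted p = 0.0123). Of 8 monocyte markers, 5 rose, including Ccr1 and Ms4a4c (2.18 ± 0.36, adjusted p = 0.00313), and Ccr2 fell (median 1.28, adjusted p = 0.000207, and adjusted p = 0.0634 with an estimated correlation). The risen members numbered 3 without resident replicate 3 or transplanted replicate 2, 3 or 4. Of 15 adhesion and matrix genes, 5 rose (7 adjusted over the list alone, median 0.36, adjusted p = 2.83e-06, and adjusted p = 0.055 with an estimated correlation). The hyaluronan receptor Cd44 stood at 18.1 ± 2.77 against 1.13 ± 0.122 CPM (3.99 ± 0.16, adjusted p = 3.73e-07) and Anxa2 at 5.91 ± 2.47 against 1.03 ± 0.315. The risen members numbered 2 without resident or transplanted replicate 3 and 3 without resident replicate 1 or 4 or transplanted replicate 4. The monocyte counts were the same adjusted over the list alone.

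H2-Aa and Cd74, of antigen presentation, and Cd163 and Lyve1, of border-associated macrophages, were lower in transplanted than in resident cells. Of 13 MHC class II and costimulation genes, 5 fell, 2 rose and 6 were not called, also adjusted over the list alone (median -0.11, mean -0.79, adjusted p = 0.0039, and adjusted p = 0.391 with an estimated correlation). With 1 library left out the median ranged from -0.21 (without transplanted replicate 2) to -0.03 (without transplanted replicate 3). H2-Aa stood at 1.91 ± 0.845 against 26.9 ± 11 CPM (-3.81 ± 0.38, adjusted p = 0.000133), H2-Eb1 at -3.79 ± 0.36, H2-Ab1 at -2.32 ± 0.27 and the invariant chain Cd74 at 28.6 ± 8.07 against 113 ± 32.9 CPM (-1.98 ± 0.24, adjusted p = 0.000421). Of 13 border-associated macrophage markers, 8 fell and 5 were not called (9 lower and 1 higher adjusted over the list alone). The list was called lower (median -1.91, adjusted p = 6.5e-14, and adjusted p = 0.0634 with an estimated correlation). Cd209f had no count in transplanted cells and was at least 139-fold lower than its 4.91 ± 1.88 CPM in resident cells. The haemoglobin scavenger receptor Cd163 stood at 0.0473 ± 0.0546 against 5.96 ± 1.92 CPM (-6.81 ± 0.51), the hyaluronan receptor Lyve1 at -4.31 ± 0.51 and the coagulation factor gene F13a1 at -4.28 ± 0.51. Without transplanted replicate 2 Lyve1 stood at -5.21 and F13a1 at -5.16, and 1 marker was called higher. Cd79b stood at 0.365 ± 0.125 against 23.1 ± 3.94 CPM (-5.96 ± 0.22, adjusted p = 3.31e-07), the 1 lymphocyte marker tested, and Pecam1 at 10.5 ± 2.23 against 47.3 ± 7.61 CPM (-2.16 ± 0.16, adjusted p = 2.31e-05).

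Interferon and MHC class I genes rose in part. Of 21 interferon response genes, 9 rose and 12 were not called (15 higher adjusted over the list alone, median 0.91, adjusted p = 6.42e-08, and adjusted p = 0.339 with an estimated correlation). Ifi204, a nucleic acid sensor, stood at 44.2 ± 13.2 against 7.94 ± 4.19 CPM (2.48 ± 0.32, adjusted p = 0.000618). The risen members numbered 2 without resident replicate 3, 3 without resident replicate 1 or 2, 4 without transplanted replicate 3 or 4 and 16 without resident replicate 4, where the median was 1.43. Of 11 MHC class I genes, 5 rose, also adjusted over the list alone (median 0.21, adjusted p = 0.00526, and adjusted p = 0.30 with an estimated correlation), with Nlrc5, the transactivator of class I genes, at 1.58 ± 0.22, H2-D1 at 0.74 ± 0.14 and H2-K1 at 0.68 ± 0.13. Of these genes 3 rose without resident replicate 1, 2 or 3 or transplanted replicate 2 or 4. Of 20 inflammatory cytokine genes, 4 rose, also adjusted over the list alone, with the receptor antagonist Il1rn at 1.81 ± 0.33, Cxcl16 at 0.98 ± 0.08 and Tlr2 at 0.98 ± 0.12. The list was not called (median -0.04 and mean -0.23, with the test in the higher direction, adjusted p = 0.0558, and p = 0.55 with an estimated correlation), and its median was 0.07 on the TPM scale. It was called higher without resident replicate 1 (median 0.40, adjusted p = 9.49e-05), transplanted replicate 1 (-0.04, 0.0369) or transplanted replicate 3 (0.03, 0.0411), and without resident replicate 1, 7 members rose and 1 fell.

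Of 32 cell cycle genes, 8 rose and 24 were not called (20 higher and 1 lower adjusted over the list alone, median 1.39, adjusted p = 0.000583, and adjusted p = 0.515 with an estimated correlation). Cdca8, a mitotic kinase partner, stood at 4.19 ± 2.57 against 1.2 ± 0.288 CPM (1.80 ± 0.40, adjusted p = 0.0142). Mki67 stood at 11.5 ± 11.1 against 3.31 ± 0.975 CPM (1.79 ± 0.54, adjusted p = 0.054), with 28.1 CPM in transplanted replicate 4 and 5.01 to 6.89 in the others. Mki67 was called without transplanted replicate 1 (2.04, adjusted p = 0.0324), 2 (2.00, 0.0388) or 4 (0.84, 0.0475). Ccnb2 was at 12.1 CPM in transplanted replicate 4 against 1.63 to 2.16, and Cenpe, a mitotic motor gene, at 11 against 2.23 to 3.07. The list median was 0.67 without this library. The risen members numbered 1 without resident replicate 1 or 2, 2 without resident replicate 3 or 4 and 17 without transplanted replicates 1 and 2. None of 20 immediate early genes was called with edgeR, DESeq2 or limma-voom, and 12 were lower at an unadjusted p under 0.05 (0 adjusted over the list alone). The list was called lower (median -2.57, adjusted p = 0.0219, and adjusted p = 0.699 with an estimated correlation), but the call rested on resident replicate 1, in which Fos, a gene chosen after its values were seen, was at 1610 CPM against 1.69 to 6.77 in the other resident libraries. Without it the median was 0 (adjusted p = 0.552), and without transplanted replicate 2 it was -2.27 (adjusted p = 0.0889). Jun stood at 261 ± 42.1 against 945 ± 1470 CPM (-1.86 ± 0.86, adjusted p = 0.191).

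Of 20 complement and phagocytic receptor genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with Axl and the anaphylatoxin receptor C5ar1 (1.10 ± 0.21, adjusted p = 0.00718) among the risen. The list was not called (median 0.04, mean 0.41, adjusted p = 0.111, and p = 0.497 with an estimated correlation), but was without resident replicate 4 (0.03, adjusted p = 0.0257). The risen members numbered 2 without resident replicate 2 or 3 and 3 without resident replicate 1 or 4 or transplanted replicate 3 or 4. Of 23 lysosome genes, 6 rose (7 adjusted over the list alone), with the glucuronidase gene Gusb at 0.40 ± 0.06 (adjusted p = 0.00243). The lysosome list was not called (median 0.14, adjusted p = 0.055, and p = 0.61 with an estimated correlation), but was without resident replicate 4 (0.17, adjusted p = 0.0278) or transplanted replicate 3 (0.12, adjusted p = 0.031). Its risen members numbered 1 without resident replicate 1, 3 or 4, 2 without resident replicate 2 or transplanted replicate 4 and 3 without transplanted replicate 2. Of 19 cholesterol synthesis genes, 3 rose, also adjusted over the list alone, with Dhcr7, which makes cholesterol, at 0.40 ± 0.08, and 1 rose without resident replicate 1, 3 or 4. The list was not called (median 0.10, adjusted p = 0.406, and p = 0.55 with an estimated correlation). Of 15 glycolysis genes, Pfkp rose (2.18 ± 0.40, adjusted p = 0.00544) and Gapdh fell (-0.36 ± 0.10, adjusted p = 0.0403), also adjusted over the list alone, and the list was not called (median -0.05, mean 0.08, test in the lower direction, adjusted p = 0.725, and p = 0.949 with an estimated correlation). Gapdh was not called without resident replicate 1, 2 or 4 or transplanted replicate 1, 2 or 4 (-0.28 to -0.37, adjusted p = 0.0618 to 0.0972). Of 12 unfolded protein and amino acid stress genes, asparagine synthetase, Asns, was called (2.11 ± 0.60, adjusted p = 0.043), as were 2 genes adjusted over the list alone. Asns was not called without any 1 resident library or transplanted replicate 3 or 4 (adjusted p = 0.065 to 0.108), and stood at 1.29 without transplanted replicate 4, which had 7.98 CPM against 0.865 to 2.89, and the list was not called (median 0.09, adjusted p = 0.478, and p = 0.738 with an estimated correlation).

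Of 27 respiratory chain genes, 6 fell (11 adjusted over the list alone, median -0.20, adjusted p = 0.000207, and adjusted p = 0.439 with an estimated correlation), with Ndufa4 at -0.44 ± 0.08 (adjusted p = 0.00539). The fallen members numbered 1 without resident replicate 2 or 4 or transplanted replicate 1, 3 or 4, and 3 without resident replicate 1. None of 25 ribosomal protein genes was called with edgeR or limma-voom and 2 were lower with DESeq2. With edgeR, 7 were lower at an unadjusted p under 0.05, and none was called adjusted over the list alone. The list was called lower (median -0.17, adjusted p = 0.0133, and adjusted p = 0.66 with an estimated correlation), though not without resident replicate 4 (-0.13, adjusted p = 0.0643) or transplanted replicate 1 (-0.13, adjusted p = 0.11). Without resident replicate 3, 1 member was lower and without transplanted replicate 3, 2 were. Neither list was called once the length trend was removed, with medians of -0.09 and -0.03.

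In 1 fit of all 3 groups Sall1, Dhcr7, Gapdh, Ndufa4, Csf3r and Cnp were not called between transplanted and resident cells. With the replicate number as a block Sall1, Gapdh, Asns and Cnp were not called. Asns was not called with limma-voom, nor Gapdh and Asns on the TPM scale, nor Gapdh and Ndufa4 with the length trend removed. The edgeR fit of all 3 groups called higher 5 interferon response, 1 lysosome, 1 cholesterol synthesis and 1 endothelial gene. It called lower 3 homeostatic genes, 1 microglial transcription factor and 0 respiratory chain genes, of which 3 were lower at an unadjusted p under 0.05.

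Astrocyte, neuron and endothelial markers gave no called list between transplanted and resident cells. None of 5 astrocyte, 5 neuron or 4 sex-linked genes was called with edgeR, DESeq2 or limma-voom, with 0 at an unadjusted p under 0.05 (list adjusted p = 0.997 for astrocyte and 0.575 for neuron markers; 0.998 and 0.649 with an estimated correlation). Of 5 endothelial markers, 3 rose and Pecam1 fell (median 0.66, with the test in the lower direction, adjusted p = 0.968, and p = 0.982 with an estimated correlation), with Flt1 at 1.85 ± 0.44. None rose without resident replicate 2, and 1 rose without resident replicate 1 or transplanted replicate 3 or 4. Of lists too small for a list test, 1 of 4 oligodendrocyte markers fell (Cnp, -0.29 ± 0.08, adjusted p = 0.048, not called without any 1 library other than transplanted replicate 2, adjusted p = 0.0506 to 0.11). Of 2 neutrophil markers, 1 rose (Csf3r, 0.42 ± 0.08, adjusted p = 0.00617), and the 1 oligodendrocyte precursor marker tested rose (Cspg4, 2.72 ± 1.54 against 0.163 ± 0.0914 CPM, 4.02 ± 0.55, adjusted p = 0.000984). Counts adjusted over the list alone were the same, and no mural cell or fibroblast marker had enough counts to be tested.

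Of 25 lists tested between transplanted and resident cells, 14 were called (8 higher, 6 lower), and none with an estimated correlation, with which 4 reached an unadjusted p under 0.05. The fry test, which tests whether a list's genes move on balance 1 way, called 10. For cultured against resident cells 18 of 27 lists were called (15 higher, 3 lower) and 4 held with an estimated correlation, and for transplanted against cultured cells 18 of 26 (3 higher, 15 lower) and 7.

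**Figure D3:**
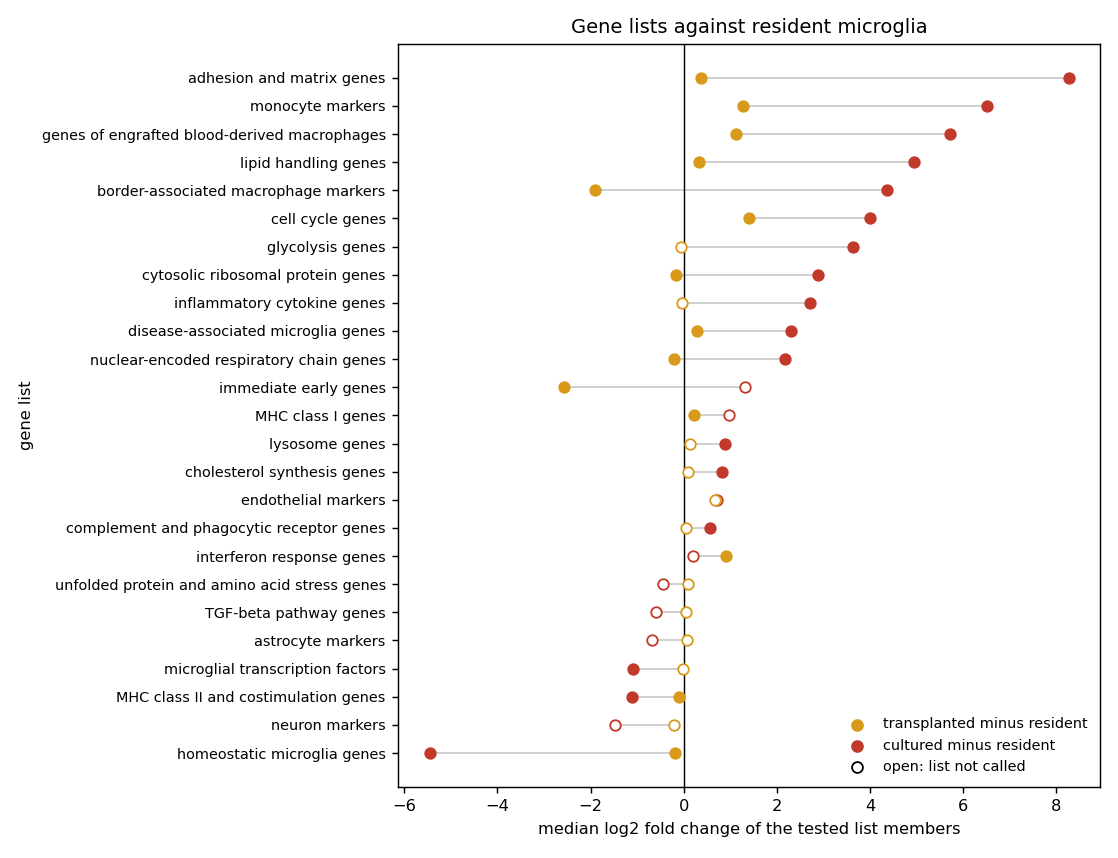
Median log2 fold change of the tested members of each list against resident microglia, for transplanted and for cultured cells; filled points are lists called by camera at its preset correlation and open points lists not called. Homeostatic genes lie at -5.44 in cultured and -0.18 in transplanted cells.

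The position of transplanted cells between the cultured level (0) and the resident level (1) was read over the 6223 genes that differed at least 2-fold between those groups. Its median over genes was 0.983, and 0.994, 0.98, 0.968 and 0.988 in the 4 transplanted libraries (SD 0.011). The source of transplanted cells is not given, so this position is a scale between groups, sorting and depth included, and not a course over time. With the resident libraries split so that those that chose the genes did not set the resident level, and the cultured libraries not split, it was 0.984 (0.975 to 0.994 over 6 splits). It was 0.98 for the 3113 genes higher in cultured cells and 0.985 for the 3110 lower, and the quartiles over genes were 0.858 and 1.07. Homeostatic genes had a median position of 0.95, glycolysis genes 1.01, ribosomal protein genes 1.05 and border macrophage markers 1.18, while cell cycle genes stood at 0.71, interferon response genes at 0.65 and genes of engrafted blood-derived macrophages at 0.75. Of these genes 299 (4.8%) lay under 0.5. Of 5723 tested between transplanted and resident cells, 4655 (81.3%) were not called and 5066 (88.5%) were within 2-fold. Of the 1068 called, 827 lay toward the cultured level and 241 away from it.

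Genes that differed between transplanted and resident cells were compared with those that differed between cultured and resident cells, over 11845 genes tested in both. Of 845 genes higher in transplanted cells, 500 (59.2%), Apoe, Axl and Ccr1 among them, were also higher in cultured cells, where independent lists would share 301.6, and 216 were lower, against 327.3. Of 699 lower genes, 479 (68.5%), Upk1b and Csmd3 among them, were also lower in cultured cells, against 270.7, and 142 higher, against 249.5. The fold changes correlated across genes at 0.409, against 0.175 in unchanged groups simulated against the same resident libraries, and at 0.377 (0.338 to 0.425) with the resident libraries split. Their covariance was 0.519, against 0.006 simulated and 0.495 with the libraries split.

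**Figure D4:**
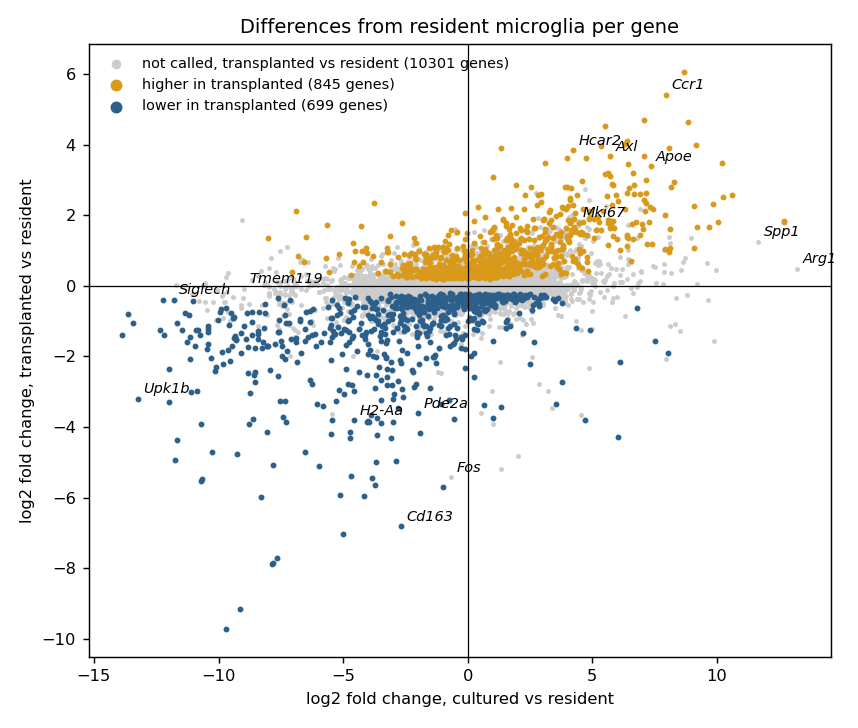
Log2 fold change of transplanted against resident cells (vertical) and of cultured against resident cells (horizontal) for genes tested in both comparisons; colour marks genes called higher or lower in transplanted cells. The correlation across genes is 0.409.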

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

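The counts of other splits were written before the results were seen, and all the other tests in this part were chosen only after. Single libraries stood far from the rest of their group in 10 of 94 groups of values examined, where chance gives about 1 in 20 groups, or 4.7. Ccr1 was at 7.05 CPM in resident replicate 2 and at 4.8 to 4.99 in the other resident libraries. Upk1b was at 188 CPM in resident replicate 1, against 222 to 229. Ncs1 was at 11.3 CPM in transplanted replicate 2, against 6.94 to 7.21. Ms4a7 was at 5.79 CPM in resident replicate 2, against 2.63 to 3.14. Mki67 was at 28.1 CPM in transplanted replicate 4, against 5.01 to 6.89. The mean log2 CPM of homeostatic microglia genes was 10.86 in resident replicate 1, against 10.97 to 10.99, and that of immediate early genes was 8.13 in the same library, against 3.56 to 3.94. Cholesterol synthesis genes had a mean of 3.73 in resident replicate 2, against 3.58 to 3.61. Lipid handling genes had a mean of 5.14 in resident replicate 2, against 4.82 to 4.84, and of 5.58 in transplanted replicate 4, against 5.25 to 5.30. In resident replicate 1 Jun was at 3150 CPM and Egr1 at 2150, where the other resident libraries had 181 to 252 and 5.62 to 17.7.

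Of 35 splits of the same libraries only the real one gave as many called genes in each comparison, the smallest share possible. The others mix the groups, which widens the spread within each side and lowers their calls. They do not show what chance alone would give. Between transplanted and resident cells the real split called 1554 genes and the highest other split 0, between cultured and resident cells 9316 and 16, and between transplanted and cultured cells 8891 and 0. For the number of called lists 2 of 35 splits gave as many in each comparison, and chance cannot be excluded. There the real and the highest other values were 14 and 14, 18 and 18, and 18 and 19 lists.

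The medians of ribosomal protein and respiratory chain genes lay above the resident level in cultured cells and below it in transplanted cells, and short transcripts as a class moved the same ways. Neither list was called between transplanted and resident cells with an estimated correlation (adjusted p = 0.66 and 0.439). Between cultured and resident cells, transcript length as the whole cause is argued against: the medians lay 0.87 (ribosomal), 0.24 (respiratory) and 2.63 (glycolysis) log2 units beyond the central 95% of 10000 random lists of equal transcript lengths. Between transplanted and resident cells the medians of -0.17 (ribosomal) and -0.2 (respiratory) were inside the central 95% of such lists, by 0.03 and 0.01. Transcript length may therefore account for those 2 small changes, and with the length trend removed neither list was called (medians -0.03 and -0.09). RNA length or quality in the groups was not tested, and a change in these pathways themselves stays open.

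Apoe, Axl, Ccr1 and Hcar2 were among the genes higher than resident in both transplanted and cultured cells. Cells or RNA in the cultured state mixed into the transplanted samples are argued against. The excess of transplanted over resident cells was taken as a share of the cultured minus the resident level. For genes abundant in cultured and scarce in resident cells its median was 0.0413% (quartiles -0.205% to 0.398%, 22 genes). These genes included Arg1 at 0.0042% and Spp1 at 0.0434%, but Apoe at 5.98% and Ccr1 at 17.2%. A set of 491 shared genes needed 23.4% (9.95% to 54.3%). The shared resident libraries as the whole cause are argued against too. The log2 differences correlated at 0.377 (0.338 to 0.425 over 6 splits) with these libraries split. Part of the cultured expression programme in the transplanted cells and a response to the depleted and repopulated brain stay open and were not tested. The labels do not give the source of the transplanted cells.

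Y-linked genes stood at an intermediate level in transplanted replicates 1 and 2, with Ddx3y at 45.1 and 31.4 CPM, against 118 and 116 in replicates 3 and 4 and 0.137 in resident replicate 4. Resident-like female cells mixed into these libraries are argued against: genes that fell in the other transplanted libraries stood at 10% and 14.1% of the resident level, far from the female shares of 58.7% and 70.3% read from Ddx3y, Kdm5d and Eif2s3y. Lower Y-linked expression in male cells stays open. Kdm5c and Eif2s3x, which have copies on both sex chromosomes and escape X inactivation, summed to 137 and 144 CPM, above the 108 to 117 of resident replicates 1 to 3 and the 123 and 113 of transplanted replicates 3 and 4, with 162 in resident replicate 4. The cultured libraries, with Ddx3y at 98.5 to 103 CPM, had 152 to 179, so the sum varies with cell state as well as sex. Kdm6a, another such gene, was at 57 and 53.2 CPM, against 15.6 to 39.4 in the cultured libraries, resident replicates 1 to 3 and transplanted replicates 3 and 4, while Ddx3x, at 133 and 144, lay among the 131 to 347 of those libraries. Transplanted cells from donors of both sexes, or host cells that repopulated the brain, stay open and were not tested.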

How the results depend on the processing

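The TPM fits, those with the length trend removed and those without transplanted replicates 1 and 2 were chosen only after the results were seen. The rest were planned. Median centring, quantile normalization and another pseudocount, planned for normalized values, were not run, since the table holds counts. The median position lay between 0.978 and 0.993 in 16 alternatives, all within the spread between libraries. Genes higher in transplanted than in resident cells stayed within 1.5 times the reported 855 in 14 of 19 alternatives, and lower genes (699) in 16 of 19. Requiring a 2-fold difference left 288 and 303 by construction, and left 3113 of the genes higher in cultured than in resident cells. In 1 fit of all 3 groups, 507 were higher and 405 lower, and without transplanted replicates 1 and 2 1374 and 1222. With 1 library left out the higher genes ranged from 511 to 875. With limma on TPM, genes higher and lower in cultured than in resident cells numbered 1993 and 7830, and in transplanted than in cultured cells 7755 and 1843, with median shifts of -1.05 and 1.04. The other changes of that fit, given above, were not taken apart. Lists called with an estimated correlation numbered 0 (transplanted against resident), 4 (cultured against resident) and 7 (transplanted against cultured). On the TPM scale Mbp stood at -0.155 between cultured and resident cells, and H2-D1 at 0.041, B2m at 0.143 and Mbp at 0.267 between transplanted and cultured cells. With the length trend removed B2m stood at -0.092 and 0.408 in those comparisons. The immediate early gene median between transplanted and resident cells ranged from -2.92 to 0 with 1 library left out, at 0 without resident replicate 1. Apart from the minimum fold, the causes of these moves were not tested. With the replicate number as a block, 707 genes were higher and 592 lower in transplanted than in resident cells, 4196 and 4271 in cultured than in resident cells, and 4139 and 4023 in transplanted than in cultured cells. Same-numbered libraries correlated at -0.07 to 0.05, and only cultured replicate 3 correlated best with its own number. Up to 25 of 97 named genes lost their call between transplanted and resident cells with 1 library left out, and at most 3 of 123 and 2 of 125 in the other comparisons. Depth limits genes near 0.136 to 0.146 CPM per library, such as Cd209f, for which a group at 0 gives a lower bound only.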

Other observations

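The tests and genes in this part were chosen only after the results were seen. Among genes that differed at least 2-fold between cultured and resident cells, some stood at the cultured level in transplanted cells. Epb41l3, which links the membrane to the cytoskeleton, was at 82.7 CPM in transplanted, 86.3 in cultured and 18.4 in resident cells (2.17 ± 0.15 against resident, adjusted p = 1.35e-05), a position of 0.02. Ms4a6c stood at 0.11 (1.13 ± 0.13, adjusted p = 0.000368), Hcar2 at 0.12 and the sorting receptor gene Sorl1 at 0.15 (1.32 ± 0.13, adjusted p = 0.000148). Mgll, which breaks down monoacylglycerols, was low in both at 44.5 and 41.4 CPM against 87.9 (-0.98 ± 0.14, adjusted p = 0.00145). Pde2a and the serine protease gene Htra3 lay beyond the cultured level, at positions of -0.75 and -0.61, with Htra3 at 80.4 CPM in transplanted, 52.4 in cultured and 25.7 in resident cells.

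Other genes moved past the resident level, away from cultured cells. Bhlhe41, a transcription factor gene, was at 404 CPM in transplanted, 212 in resident and 83.9 in cultured cells (0.93 ± 0.10 against resident, adjusted p = 0.000191), a position of 1.68. The fatty acid receptor gene Gpr84 was at 327, 141 and 32.9 CPM (1.22 ± 0.22, adjusted p = 0.0054), the sulfotransferase gene Chst1 at 39.4, 11.6 and 1.82 (1.77 ± 0.17, adjusted p = 0.000119) and Pvrig at 68.7, 27.2 and 5.98 (1.34 ± 0.11, adjusted p = 2.98e-05). Slamf8 and Slamf9, of the SLAM receptor family, had positions of 1.55 and 1.53.

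Levels were also summed over markers of other cell types, without a test. Border-associated macrophage markers summed to 661 ± 48.3 CPM in resident and 527 ± 114 in transplanted cells, little of it Cd163 or Lyve1. Monocyte markers summed to 27.5 ± 5.56 and 268 ± 94.7, most of the latter from Ccr1 at 231. Lymphocyte markers summed to 24.9 ± 4.6 and 2.41 ± 0.27 and endothelial markers to 59.9 ± 7.8 and 31.6 ± 2.47. Most of these resident sums were Cd79b and Pecam1. Neutrophil markers summed to 796 and 1060, nearly all Csf3r at 792 and 1060.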
